A study of Arabidopsis thaliana with 15 samples.

How the data were processed

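RNA was prepared from whole Arabidopsis thaliana seedlings after 5 days in continuous white light of 100 µE on MS medium with 1% sucrose, per the labels' protocols. Cy3-labelled cRNA was made from 0.5 µg total RNA and hybridized to Agilent arrays, 1 array per sample and 3 samples in each of 5 genotypes. The intensity values were made with Agilent Feature Extraction 10.5.1.1 per the file headers, which subtracted background and corrected spatial trends within each array and did not normalize between arrays. All 15 columns of values deposited for the series equalled these processed intensities, so they were not analysed as a separate source. Steps beyond those in the headers are not given in the sources used here. The median of the deposited intensity was 653, 726 and 721 for wild type replicates 1 to 3, 786, 722 and 748 for ga1, 691, 664 and 613 for pif1345, 627, 768 and 704 for GNC-GFP, and 585, 431 and 578 for YFP-GNL. Each array had 2 to 13 flagged spots, whose values were left out, and 0 saturated spots. The median coefficient of variation of replicate spots on an array was 6.02% to 16.0%.

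Each array held 45220 features, of which 43803 were gene spots of 43603 distinct probes, and 50 probes were printed on 5 spots each. The log2 of the processed intensity was taken and the array's 75th percentile over gene spots was subtracted. Spots of 1 probe were averaged. Gene names came from the array annotation and the reference list of locus tags. Of the probes, 34185 matched 1 locus, 0 matched several, and 9418 were not named here. The named probes covered 25347 loci, 6874 of them with several probes. A probe was kept where it was well above background on all 3 arrays of at least 1 genotype, which left 30802 probes. For each locus the probe with the highest mean signal was tested, which gave 22450 genes, with 15 gene values missing through flags. A fold change against a genotype where no array was well above background is given as a lower bound.

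All 15 arrays were fitted together in limma 3.58.1 under R 4.3.3, with data.table (version 1.17.8) for reading, a mean for each genotype and 10 residual degrees of freedom (11.83 with the prior). The contrasts were each genotype against wild type and the 6 direct contrasts between the other genotypes. Empirical Bayes moderated tests, 2-sided, were adjusted by Benjamini and Hochberg's method, with a threshold of 0.05, and genes at 2-fold or more were also counted. For shared changes, genes past the threshold in the same direction in a pair of contrasts were counted. This number stands beside that for independent lists and beside 100 simulations of unchanged groups against the same wild type arrays.

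The gene lists, 23 with 337 members, of which 331 were tested, were written from general knowledge before the data were examined, as were the model, the contrasts, the rule for naming genes and the alternatives below named as planned. Some loci are in more than 1 list. Lists were tested with limma's camera at its preset correlation between genes of 0.01 and, as an alternative, with an estimated correlation. The p-values were adjusted over 92 tests against wild type and, separately, over 138 tests of direct contrasts. Genes are named by rule: the genes of the genotypes; the 10 largest increases and decreases against wild type among genes past the threshold, well above background and without overlap between groups; up to 4 members of each list with the smallest adjusted p; the 3 largest each way in a direct contrast; and 5 each way for each shared pair. Members named for lists in direct contrasts, the genes named as shared by all 4 genotypes, late embryogenesis abundant (LEA) genes and neighbours of LHCB4.1 were chosen after their values, or those of related genes, were seen.

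Alternatives planned were another background correction (normexp, offset 50), quantile normalization, no filter on dim probes, replicate number as a block, slide as a block, only the groups compared, a variance trend, the mean of all probes of a gene, leaving out each array, and an estimated correlation for lists. The planned normexp correction named a mean signal column that the files do not hold, and the median signal was used. Chosen after seeing the data were fits within 1 slide and counts without the dimmest 10% of genes (2245 genes, which leaves 20205). So was normexp without control spots read as covered by dust. The slide cannot be used as a block against wild type, whose arrays are alone on slide 1. Slide differences were therefore removed only from direct contrasts, and as a random block elsewhere for genes.

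The scripts were tested on simulated data with 22450 genes and 50 changed genes for each fold size. In the simulated contrast of ga1 with wild type, 72% of genes changed 1.5-fold, 90% of those changed 2-fold, 100% changed 4-fold and 100% changed 8-fold were recovered. For pif1345 the shares were 74%, 80%, 94% and 100%, for GNC-GFP 66%, 90%, 98% and 100%, and for YFP-GNL 68%, 84%, 92% and 100%. False calls were 4.93%, 4.50%, 6.09% and 4.19% of the calls in these contrasts. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 under Python 3.11.15.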

Results

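Transcript levels were measured in whole 5-day-old Arabidopsis thaliana seedlings of 5 genotypes, each on 3 single-colour Agilent arrays, 15 arrays in all. The genotypes included wild type and the mutant ga1, both labelled with the Col accession in the sample titles. The mutant ga1 is named for the gene of an early enzyme of gibberellin (GA) synthesis. The mutant pif1345 is named for the phytochrome-interacting transcription factors PIF1, PIF3, PIF4 and PIF5. The others were transgenic lines named for the GATA transcription factors GNC, fused to GFP, and GNL, fused to YFP. The sample titles give no accession for pif1345 or the transgenic lines. The series title presents the transgenic lines as overexpression of GNC and GNL, to be compared with both mutants. Between 78.8% and 85.4% of the gene spots of an array were well above background, and the 75th percentile of the signal lay between 2605 and 4343 units. Arrays of 1 genotype correlated at 0.990 or higher, and the lowest correlation between arrays of different genotypes was 0.941. With 3 arrays per genotype, the number of arrays limits the precision, and the median standard error of a log2 difference was 0.0895. The design text speaks of 3 biological samples for each genotype; where arrays of a genotype did not come from separate cultures, the p-values measure only the spread between these arrays.

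The 15 arrays lay on 4 slides. The wild type arrays were alone on slide 1, so a difference seen only against wild type cannot be told apart from a property of that slide. Slide 2 held the ga1 arrays and pif1345 replicate 3, slide 3 held pif1345 replicates 1 and 2 with YFP-GNL replicates 2 and 3, and slide 4 held the GNC-GFP arrays with YFP-GNL replicate 1. Direct contrasts on 1 slide do not involve wild type. Slide 4 has 1 YFP-GNL array and slide 2 has 1 pif1345 array, so direct tests there assume that the lone sample varies like the other groups. No slide holds GNC-GFP with ga1 or pif1345, or YFP-GNL with ga1. For these pairs a value with slide as a block is indirect. It is linked through YFP-GNL replicate 1 for GNC-GFP against pif1345, through pif1345 replicate 3 for YFP-GNL against ga1, and through both arrays for GNC-GFP against ga1. Below, a log2 fold change is the mean of the first genotype minus that of the second, ± its standard error, with n = 3 arrays per genotype, and each adjusted p comes from limma.

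Transcripts of the genes named in the genotypes were examined first. In pif1345, PIF1 (AT2G20180) had a log2 fold change of -4.84 ± 0.093 against wild type, PIF3 (AT1G09530) -3.67 ± 0.10, PIF4 (AT2G43010) -3.56 ± 0.14 and PIF5 (AT3G59060) -7.12 ± 0.10, with adjusted p from 2.21e-12 to 5.19e-08. In YFP-GNL, the GNL transcript (AT4G26150) was 151-fold higher than in wild type (log2 7.24 ± 0.12, adjusted p = 3.27e-12). In GNC-GFP, the brighter GNC probe (AT5G56860) was 6.26-fold higher (log2 2.65 ± 0.12, adjusted p = 1.42e-07), while the other GNC probe had a log2 fold change of -1.60. GNL fell in GNC-GFP (log2 -1.45 ± 0.12) and GNC fell in YFP-GNL, with values of -3.56 and -3.59 on its probes. In ga1 the GA1 transcript (AT4G02780) was 7.35-fold higher than in wild type (log2 2.88 ± 0.27, adjusted p = 1.41e-06). The labels used here do not give the lesion of ga1, and where the probe lies relative to it is not known, so this value checks nothing about the label.

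**Figure D1:**
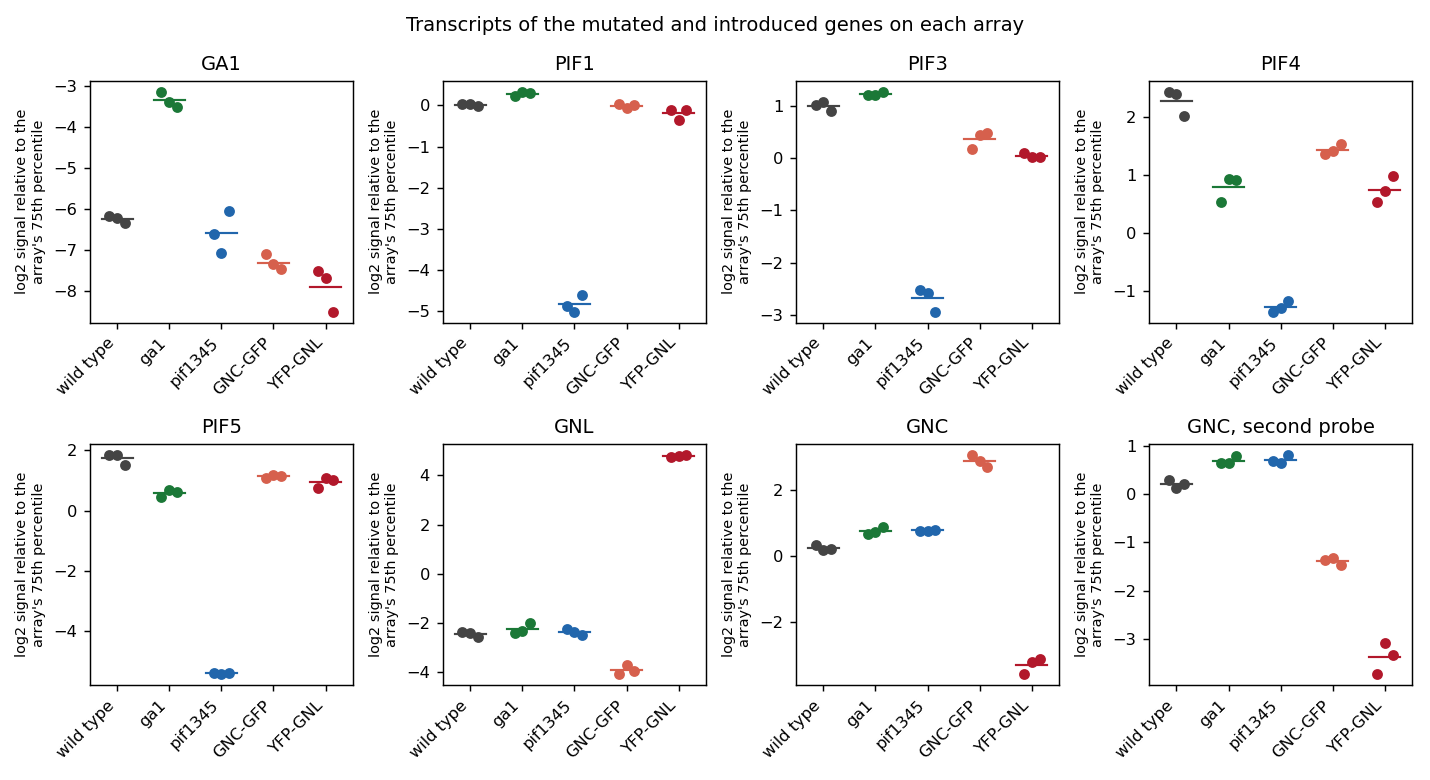
Each panel shows 1 gene probe, with the log2 signal relative to the array's 75th percentile on the vertical axis and the 5 genotypes on the horizontal axis; points are arrays and lines are means of 3 arrays. The PIF transcripts are lowest in pif1345, GNL is 151-fold higher in YFP-GNL than in wild type, and the probes of GNC go in opposite directions in GNC-GFP.

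The same genes also differed in the other lines. PIF4 fell in ga1 (log2 -1.49 ± 0.14), GNC-GFP (-0.85 ± 0.14) and YFP-GNL (-1.54 ± 0.14), and PIF5 fell in these lines by values of -1.14, -0.59 and -0.78. PIF3 fell in GNC-GFP (log2 -0.63) and YFP-GNL (-0.96), with a value of 0.23 in ga1 that did not pass (adjusted p = 0.067). GNC rose in ga1 (log2 0.52, adjusted p = 0.00176) and in pif1345 (log2 0.53, adjusted p = 0.00433). GA1 fell in GNC-GFP (log2 -1.06, adjusted p = 0.0040) and was not well above background on any YFP-GNL array, where it was at least 2.51-fold lower than in wild type (adjusted p = 1.17e-04). PIF1 rose in ga1 by 0.27 (adjusted p = 0.0189), a call lost without wild type replicate 3 (adjusted p = 0.0525) or ga1 replicate 2 (adjusted p = 0.0558).

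In ga1 seedlings, transcripts of the anthocyanin pathway were higher than in wild type and those of shade, auxin and cell wall genes were lower. All 16 tested genes of the flavonoid and anthocyanin list rose, with a median log2 fold change of 2.34 (camera adjusted p = 2.82e-05, adjusted p = 0.497 with an estimated correlation). GSTF12, needed for anthocyanin transport into the vacuole, rose by 3.34 ± 0.23, the bHLH regulator TT8 by 2.91 ± 0.20 and the flavonoid hydroxylase TT7 by 2.33 ± 0.15. Of 22 tested PIF and shade targets, 21 fell and 1 rose, with a median of -1.65 (camera adjusted p = 4.87e-08, adjusted p = 0.446 with an estimated correlation). The homeodomain genes HB4 (log2 -3.09 ± 0.16), HB-2 (-2.76 ± 0.18) and HAT3 (-1.65 ± 0.085) were among them, as was PAR1 (-2.06 ± 0.13).

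Auxin response genes fell in ga1, 21 of 23 tested and none rising, with a median log2 fold change of -1.24 (camera adjusted p = 6.23e-08, adjusted p = 0.446 with an estimated correlation). SAUR19, a small auxin-induced gene, fell with a value of -2.78 ± 0.19 and the auxin-conjugating enzyme gene WES1 with -1.73 ± 0.091. Among 23 cell wall loosening genes 16 fell and 3 rose. The members had a median of -0.84 (camera adjusted p = 0.00743, adjusted p = 0.493 with an estimated correlation), with the expansin genes EXPA2 at -3.65 ± 0.31 and EXPA8 at -2.47 ± 0.17 and the xyloglucan enzyme gene XTH31 at 1.44 ± 0.12. Of 20 genes of light-harvesting proteins, 18 fell and 1 rose in ga1 (median -0.52, camera adjusted p = 1.82e-04, adjusted p = 0.582 with an estimated correlation). LHCB2.3 had a value of -2.45 ± 0.14, LHCB4.2 of -1.49 ± 0.11 and LHCB4.3, the member that rose, of 2.06 ± 0.14. Cytokinin response genes numbered 9 that fell and 1 that rose of 13. All members together had a median of -0.92 (camera adjusted p = 0.0106, adjusted p = 0.446 with an estimated correlation). The genes that passed included the response regulator genes ARR15 (-0.97 ± 0.091) and ARR7 (-0.92 ± 0.082). Root markers fell for 13 of 18 genes and rose for 2. The median over the list was -0.96 (camera adjusted p = 0.0162, adjusted p = 0.627 with an estimated correlation). Among the members were the Casparian strip gene CASP1 (-1.51 ± 0.28).

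Seed maturation genes rose in ga1 for 14 of 18 genes and fell for none (median 1.495, camera adjusted p = 0.0280, adjusted p = 0.616 with an estimated correlation). The regulators LEC1 and ABI3 rose by 1.36 ± 0.17 and 0.72 ± 0.11, and the 2S albumin gene SESA1 was at least 10.9-fold higher. This list's call was lost without wild type replicate 3 (adjusted p = 0.0513) or ga1 replicate 1 (adjusted p = 0.0555). In the GA biosynthesis list 6 of 11 genes rose and 1 fell (median 0.31, camera adjusted p = 0.323), with the late-step oxidase genes GA20OX3 at 3.47 ± 0.36 and GA3OX1 at 1.81 ± 0.11. For GA inactivation, 2 of 7 genes rose and 3 fell (median -0.16, camera adjusted p = 0.364), and GA2OX8 had a value of -1.69 ± 0.15. For GA perception and DELLA genes, 3 of 13 rose and 7 fell (median -0.29, camera adjusted p = 0.155), among them the DELLA genes GAI at -1.35 ± 0.095 and RGL3 at -0.91 ± 0.053. Chlorophyll biosynthesis genes rose for 17 and fell for 7 of 24 (median 0.54, camera adjusted p = 0.0847), and plastid development and division genes rose for 10 and fell for 5 of 16 (median 0.42, camera adjusted p = 0.364). B-class GATA genes rose for 4 of 7 (median 0.22, camera adjusted p = 0.205). With p adjusted over each list alone, the counts for ga1 were the same in every list except cytokinin response, where 2 rose and 9 fell.

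Apart from list members, large increases in ga1 were those of ESP (AT1G54040), which directs glucosinolate breakdown, at 149-fold (log2 7.22 ± 0.21, adjusted p = 4.61e-10), the glucose-phosphate translocator gene GPT2 at 48.6-fold and SQN, a cyclophilin gene, at 41.4-fold. The wax hydroxylase gene CYP96A15 rose by 4.94 ± 0.34, the cold-regulated COR15A by 4.53 ± 0.29, the early light-induced ELIP1 by 4.13 ± 0.28 and CORI3 by 3.90 ± 0.22. Large decreases were those of the marneral synthase gene MRN1 (log2 -7.22 ± 0.93, adjusted p = 2.16e-05), the cutinase gene CDEF1 (-4.86 ± 0.15), the asparagine synthetase gene ASN1 (-4.64 ± 0.42) and NSP3 (-4.33 ± 0.39). The flowering repressor gene FLC fell to a 14.4-fold lower level (log2 -3.85 ± 0.14) and CYP71A16, the marneral oxidase gene, had a value of -3.73 ± 0.50. In all, 16702 of 22450 tested genes passed in ga1, 9432 higher and 7270 lower, and 2959 were at least 2-fold higher and 1822 at least 2-fold lower. The dimmest 10% of the genes held 40.5% of the 2-fold increases; without it, 1761 genes were at least 2-fold higher and 1663 lower, and with quantile normalization over all genes the numbers were 2048 and 2213.

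In pif1345 seedlings, PIF and auxin targets were lower than in wild type and seed storage transcripts were higher. Of 22 PIF and shade targets 20 fell and none rose (median -1.54, camera adjusted p = 2.89e-16, adjusted p = 0.446 with an estimated correlation). The auxin biosynthesis gene YUC8 had a value of -2.22 ± 0.13, HB4 of -2.34 ± 0.16, HAT3 of -1.23 ± 0.085 and PIL1 of -2.57 ± 0.22. Auxin response genes fell for 22 of 23. For the whole list the median was -0.80 (camera adjusted p = 4.84e-15, adjusted p = 0.446 with an estimated correlation), with IAA29, which belongs to both lists, at -3.96 ± 0.25, IAA19 at -1.62 ± 0.11 and SAUR19 at -1.98 ± 0.19. Cell wall loosening genes fell for 13 of 23 and rose for 1. Across the list the median was -0.38 (camera adjusted p = 0.00133, adjusted p = 0.446 with an estimated correlation). Members that passed included EXPA8 at -1.60 ± 0.17 and TCH4 at -1.35 ± 0.22.

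Seed maturation genes rose for 16 of 18 in pif1345 and fell for none, with a median log2 fold change of 4.56 (camera adjusted p = 1.11e-08, adjusted p = 0.446 with an estimated correlation). The 2S albumin genes SESA3 (AT4G27160) and SESA4 (AT4G27170) had values of 8.06 ± 0.71 and 7.26 ± 0.62, the cruciferin gene CRU3 (AT4G28520) of 6.70 ± 0.81 and the oleosin gene OLEO1 (AT4G25140) of 6.06 ± 0.78, with adjusted p from 2.24e-05 to 2.10e-04. SESA1 was at least 70.6-fold higher. Single arrays moved several of these values: SESA4 was 6.58 without pif1345 replicate 2, CRU3 was 6.07 without wild type replicate 2, and OLEO1 was 5.39 without pif1345 replicate 2 and 6.80 without replicate 3.

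**Figure D2:**
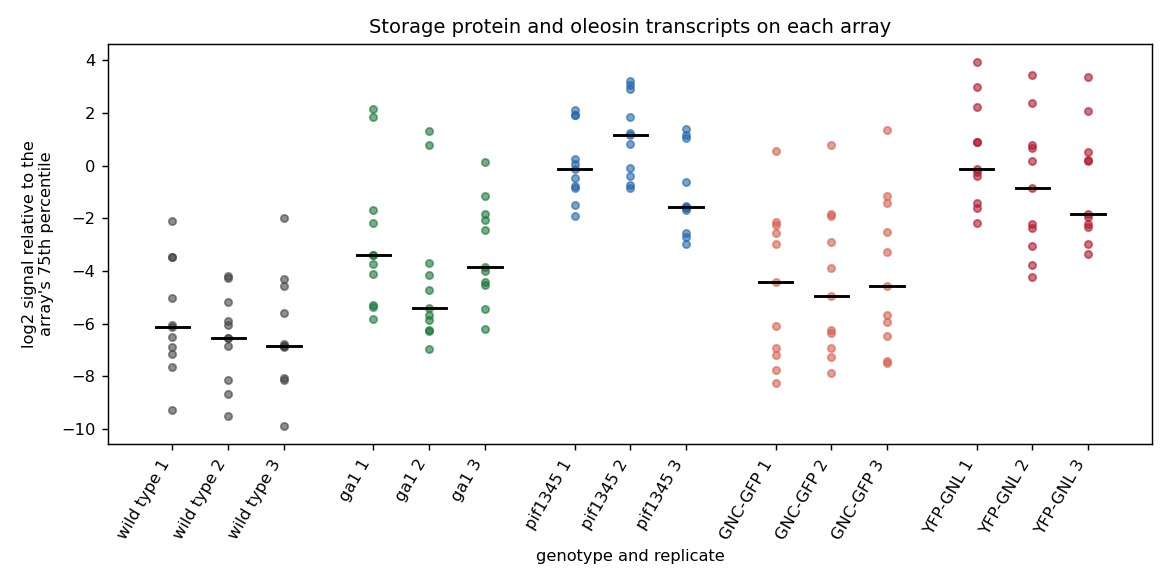
Points are the storage protein and oleosin genes on each of the 15 arrays, with the log2 signal relative to the array's 75th percentile on the vertical axis and the median of each array as a black line. The medians lie between -6.86 and -6.13 on the wild type arrays, between -1.56 and 1.16 in pif1345 and between -1.85 and -0.11 in YFP-GNL.

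Light-harvesting genes fell for 11 of 20 in pif1345 and rose for 1 (median -0.27, camera adjusted p = 2.69e-04, adjusted p = 0.594 with an estimated correlation), LHCB2.3 with a value of -1.67 ± 0.14 and LHCB3 of -0.66 ± 0.074. Plastid development and division genes rose for 9 of 16 and fell for 1. The list's median log2 fold change was 0.21 (camera adjusted p = 0.0228, adjusted p = 0.493 with an estimated correlation). Its members included the plastid division gene FTSZ1-1 (0.47 ± 0.060) and the sigma factor gene SIGF (0.49 ± 0.067). The call of this list was lost without wild type replicate 3 (adjusted p = 0.0632). GA perception and DELLA genes fell for 5 of 13 and rose for 1. The list had a median of -0.24 (camera adjusted p = 0.0106, adjusted p = 0.446 with an estimated correlation), with GAI at -0.88 ± 0.095 and RGL3 at -0.78 ± 0.053. Chlorophyll biosynthesis genes rose for 9 and fell for 4 of 24 (median 0.13, camera adjusted p = 0.205), with GSA1 at 0.55 ± 0.082 and the chlorophyll b synthesis gene CH1 at -0.69 ± 0.085. GA biosynthesis genes rose for 2 and fell for 6 of 11 (median -0.21, camera adjusted p = 0.109). GA inactivation genes rose for 1 and fell for 2 of 7 (median 0.02, camera adjusted p = 0.470, test directed down). Cytokinin response genes rose for 2 and fell for 6 of 13 (median -0.28, camera adjusted p = 0.0595). Flavonoid and anthocyanin genes rose for 8 and fell for 1 of 16 (median 0.20, camera adjusted p = 0.374). Root markers fell for 3 of 18 (median -0.18, camera adjusted p = 0.205), and B-class GATA genes rose for 4 of 7 (median 0.26, camera adjusted p = 0.0560). These counts were the same with p adjusted over each list alone, except for GA perception and DELLA, where 1 rose and 6 fell.

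Outside the lists, QQS, a gene that affects starch content, rose in pif1345 by 6.08 ± 0.29 (67.5-fold, adjusted p = 3.59e-07). Besides the PIF genes, large decreases included those of CYP96A5 (log2 -3.74 ± 0.40), PGL2 (-3.67 ± 0.082), the ethylene biosynthesis gene ACS8 (-3.17 ± 0.32) and RTFL21 (-2.34 ± 0.29). In all, 8850 genes passed, 5292 higher and 3558 lower, with 856 at least 2-fold higher and 241 at least 2-fold lower. Without the dimmest 10% of genes, which held 55.4% of the 2-fold increases, 382 were at least 2-fold higher and 187 lower, and with quantile normalization over all genes the numbers were 379 and 321.

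GNC-GFP seedlings had higher transcripts of chlorophyll and plastid genes and lower transcripts of PIF and auxin targets than wild type. Chlorophyll biosynthesis genes rose for 16 of 24 and fell for 5. The members had a median of 0.45 (camera adjusted p = 0.0340, adjusted p = 0.616 with an estimated correlation). The genes that passed included the magnesium chelatase gene ALB1 (0.58 ± 0.055), the chlorophyll synthase gene G4 (0.66 ± 0.073) and the protochlorophyllide reductase gene POR C (0.62 ± 0.078). This list did not pass when only GNC-GFP and wild type arrays were fitted (adjusted p = 0.101). Plastid development and division genes rose for 12 of 16 and fell for 2. All members together had a median of 0.50 (camera adjusted p = 0.0106, adjusted p = 0.446 with an estimated correlation), with FTSZ2-1 at 0.86 ± 0.066, ARC6 at 0.75 ± 0.058 and SIG4 at 0.95 ± 0.079. Light-harvesting genes rose for 1 and fell for 6 of 20 (median -0.09, camera adjusted p = 0.0816).

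PIF and shade targets fell in GNC-GFP for 17 of 22 and rose for 1 (median -0.79, camera adjusted p = 6.80e-05, adjusted p = 0.493 with an estimated correlation). HFR1, a bHLH gene of light signalling, had a value of -2.50 ± 0.17, PAR1 of -2.15 ± 0.13, FHL of -2.24 ± 0.25 and HB4 of -1.70 ± 0.16. Auxin response genes fell for 16 of 23 and rose for 1. The median over the list was -0.53 (camera adjusted p = 0.00282, adjusted p = 0.616 with an estimated correlation), with IAA6 at -1.56 ± 0.20 and IAA19 at -0.91 ± 0.11, while the conjugating enzyme gene GH3.3 rose by 1.00 ± 0.086. Cell wall loosening genes fell for 13 of 23 and rose for 2. For the whole list the median was -0.48 (camera adjusted p = 0.0187, adjusted p = 0.511 with an estimated correlation). Among the members were XTH4 (-1.29 ± 0.12) and EXPA11 (-1.24 ± 0.20). Cytokinin response genes fell for 7 of 13. Across the list the median was -0.45 (camera adjusted p = 0.0224, adjusted p = 0.446 with an estimated correlation). Members that passed included RR5 (-0.98 ± 0.10) and ARR6 (-0.57 ± 0.095). GA perception and DELLA genes fell for 7 of 13. The list's median log2 fold change was -0.22 (camera adjusted p = 0.0112, adjusted p = 0.446 with an estimated correlation), with GAI at -0.90 ± 0.095 and RGL1 at -0.70 ± 0.10.

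Seed maturation genes rose for 13 of 18 in GNC-GFP and fell for none (median 1.23, and 1.03 with genes below background at their bounds; camera adjusted p = 0.0300, adjusted p = 0.616 with an estimated correlation). The regulators FUS3 (1.27 ± 0.16) and LEC1 (1.19 ± 0.17) rose, as did the cruciferin gene CRA1 (3.67 ± 0.60), which had a value of 2.93 without wild type replicate 2. The call of the list was lost without wild type replicate 3 (adjusted p = 0.0515), without GNC-GFP replicate 3 (adjusted p = 0.0555) and with the mean of all probes (adjusted p = 0.0824). GA biosynthesis genes rose for 3 and fell for 5 of 11 (median 0.01, mean -0.05, camera adjusted p = 0.744), with GA20OX2 at -1.16 ± 0.10 and KAO2 at 0.52 ± 0.062. GA inactivation genes rose for 3 and fell for 4 of 7 (median -0.70, camera adjusted p = 0.534). Flavonoid and anthocyanin genes rose for 4 and fell for 1 of 16 (median 0.04, camera adjusted p = 0.889). Root markers fell for 6 of 18 (median -0.46, camera adjusted p = 0.0524), and B-class GATA genes rose for 2 and fell for 5 of 7 (median -0.45, camera adjusted p = 0.130). Adjusted over the list alone, 18 PIF and shade targets fell and 1 rose, 2 root markers fell, and 3 flavonoid genes rose and 1 fell; the other lists named here for GNC-GFP kept their numbers.

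The lipid transfer protein gene LTP4 rose 53.5-fold in GNC-GFP (log2 5.74 ± 0.52, adjusted p = 2.93e-06). The kinase gene MPK10 rose by 4.05 ± 0.18, the auxin glucosyltransferase gene UGT74E2 by 3.84 ± 0.35, COR15B by 3.47 ± 0.20 and GPT2 by 3.42 ± 0.34. The iron-deficiency bHLH gene bHLH39 rose by 3.31 ± 0.70; its relative BHLH100 rose by 3.52 ± 1.25 (adjusted p = 0.0266), a call lost without wild type replicate 2 (adjusted p = 0.0945), GNC-GFP replicate 1 (adjusted p = 0.0606), replicate 2 (adjusted p = 0.0503) or replicate 3 (adjusted p = 0.0633). Large decreases were those of ASN1 (-2.88 ± 0.42), the dark-induced SEN1 (AT4G35770; -2.55 ± 0.29), HFR1, the glyoxylate cycle gene ICL (-2.49 ± 0.44, and -1.78 without wild type replicate 3) and the threonine aldolase gene THA1 (-2.41 ± 0.39). In all, 14492 genes passed, 8058 higher and 6434 lower, with 1853 at least 2-fold higher and 752 at least 2-fold lower. Without the dimmest 10% of genes, which held 44.1% of the 2-fold increases, 1036 were at least 2-fold higher and 658 lower, and with quantile normalization over all genes the numbers were 1112 and 1036.

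YFP-GNL seedlings had higher transcripts of chlorophyll, plastid, stomatal lineage and seed maturation genes and lower transcripts of PIF, auxin and root genes than wild type. Chlorophyll biosynthesis genes rose for 17 of 24 and fell for 3. The list had a median of 0.72 (camera adjusted p = 0.0030, adjusted p = 0.497 with an estimated correlation), with GSA2 at 1.25 ± 0.098, GSA1 at 1.103 ± 0.082, HEMC at 1.06 ± 0.069 and CHLI1 at 0.86 ± 0.066. Plastid development and division genes rose for 12 of 16 and fell for 3. The members had a median of 0.72 (camera adjusted p = 0.0106, adjusted p = 0.446 with an estimated correlation). Its members included FTSZ2-1 (1.097 ± 0.066), FTSZ1-1 (1.06 ± 0.060) and ARC6 (1.01 ± 0.058). Light-harvesting genes rose for 4 and fell for 6 of 20, with a median of 0.08, a mean of -0.40 and a test directed down (camera adjusted p = 0.713). LHCB4.1 (AT5G01530), of the minor antenna CP29, was 149-fold lower (log2 -7.22 ± 0.10, adjusted p = 1.68e-12), LHCB2.3 had a value of -1.31 ± 0.14, and LHCB4.3 rose by 0.69 ± 0.14. All 7 stomatal lineage genes rose. All members together had a median of 0.97 (camera adjusted p = 0.0151, adjusted p = 0.497 with an estimated correlation), with MUTE, which ends the stem-like divisions of the lineage, at 1.63 ± 0.094 and the peptide gene EPF1 at 1.13 ± 0.059.

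Seed maturation genes rose for 17 of 18 in YFP-GNL and fell for none (median 4.98, and 4.85 with genes below background at their bounds; camera adjusted p = 6.80e-05, adjusted p = 0.446 with an estimated correlation). CRU3 rose by 7.12 ± 0.81, SESA3 by 6.86 ± 0.71, OLEO1 by 6.75 ± 0.78, CRA1 by 6.37 ± 0.60 and ABI3 by 1.82 ± 0.11, and SESA1 was at least 26.3-fold higher. Without wild type replicate 2, CRU3 had a value of 6.50 and CRA1 of 5.63; without YFP-GNL replicate 1, SESA3 had a value of 6.19.

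PIF and shade targets fell for 19 of 22 in YFP-GNL and rose for none. The median over the list was -1.27 (camera adjusted p = 2.19e-06, adjusted p = 0.446 with an estimated correlation), with HFR1 at -3.11 ± 0.17, HB4 at -2.93 ± 0.16 and PAR1 at -2.59 ± 0.13, and FHL was at least 8.63-fold lower. Auxin response genes fell for 18 of 23 and rose for 1 (median -0.95, camera adjusted p = 6.80e-05, adjusted p = 0.532 with an estimated correlation), IAA6 with a value of -2.78 ± 0.20 and SAUR9 of -1.62 ± 0.15. Cell wall loosening genes fell for 14 of 23 and rose for 4. For the whole list the median was -0.42 (camera adjusted p = 0.0146, adjusted p = 0.497 with an estimated correlation). The genes that passed included EXPA11 (-2.35 ± 0.20) and XTH33 (-1.40 ± 0.13). Root markers fell for 16 of 18 and rose for 1. Across the list the median was -1.06 (camera adjusted p = 0.00588, adjusted p = 0.614 with an estimated correlation). Among the members were RSL4, a root hair regulator (-1.89 ± 0.33), and MYB36, an endodermis regulator (-1.37 ± 0.15). Cytokinin response genes fell for 9 of 13 and rose for 1. The list's median log2 fold change was -0.50 (camera adjusted p = 0.0162, adjusted p = 0.446 with an estimated correlation), with RR5 at -1.39 ± 0.10 and ARR6 at -1.30 ± 0.095. GA perception and DELLA genes fell for 8 of 13. The list had a median of -0.30 (camera adjusted p = 0.0284, adjusted p = 0.446 with an estimated correlation), with GAI at -1.31 ± 0.095 and the receptor gene GID1A at -0.58 ± 0.054; with quantile normalization this list did not pass (adjusted p = 0.0577).

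GA biosynthesis genes rose for 3 and fell for 5 of 11 in YFP-GNL (median 0.02, camera adjusted p = 0.641, test directed down), with GA20OX3 at 3.49 ± 0.36 and GA20OX2 at -1.48 ± 0.10. GA inactivation genes rose for 3 and fell for 4 of 7 (median -1.18, and -0.76 with a gene below background at its bound; camera adjusted p = 0.374), and ATGA2OX1 had a value of -1.27 ± 0.091. Flavonoid and anthocyanin genes rose for 7 and fell for 5 of 16 (median -0.01, camera adjusted p = 0.949, test directed up), with TT4 at 1.06 ± 0.18 and DFR at -1.60 ± 0.26. B-class GATA genes rose for 1, GNL itself, and fell for 5 of 7 (median -0.71, camera adjusted p = 0.0857), among them GATA16 at -2.48 ± 0.11 and GATA15 at -1.27 ± 0.075. The numbers for YFP-GNL with p adjusted over each list alone were the same in these lists except light-harvesting proteins, where 4 rose and 5 fell.

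Outside the lists, DSI-1VOC rose by 6.015 ± 0.51, MPK10 by 5.63 ± 0.18 and the beta-glucosidase gene BGLU19 by 6.03 ± 1.33 in YFP-GNL. Besides LHCB4.1, large decreases were those of the sulfotransferase gene ST4B (-4.78 ± 0.70, -5.61 without YFP-GNL replicate 1 and -3.80 without replicate 2), FAMT (-4.23 ± 0.57), COR413IM1 (-4.10 ± 0.31), CORI3 (-4.06 ± 0.22), SEN1 (AT4G35770; -4.02 ± 0.29) and NAM (-3.91 ± 0.12). In all, 16920 genes passed, 9111 higher and 7809 lower, with 2619 at least 2-fold higher and 2298 at least 2-fold lower. Without the dimmest 10% of genes, which held 28.0% of the 2-fold increases, 1887 were at least 2-fold higher and 2059 lower, and with quantile normalization over all genes the numbers were 1981 and 2417.

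**Figure D3:**
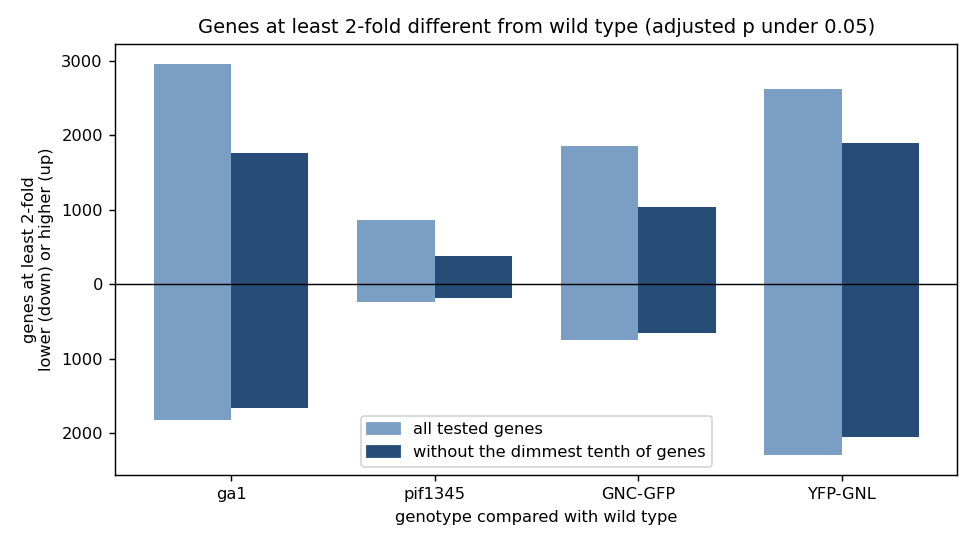
Bars give the number of genes at least 2-fold higher (up) or lower (down) than wild type with adjusted p under 0.05 in each genotype, for all tested genes and without the dimmest 10%. In ga1 the increases number 2959 over all genes and 1761 without the dimmest 10%, and the decreases 1822 and 1663.

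**Figure D4:**
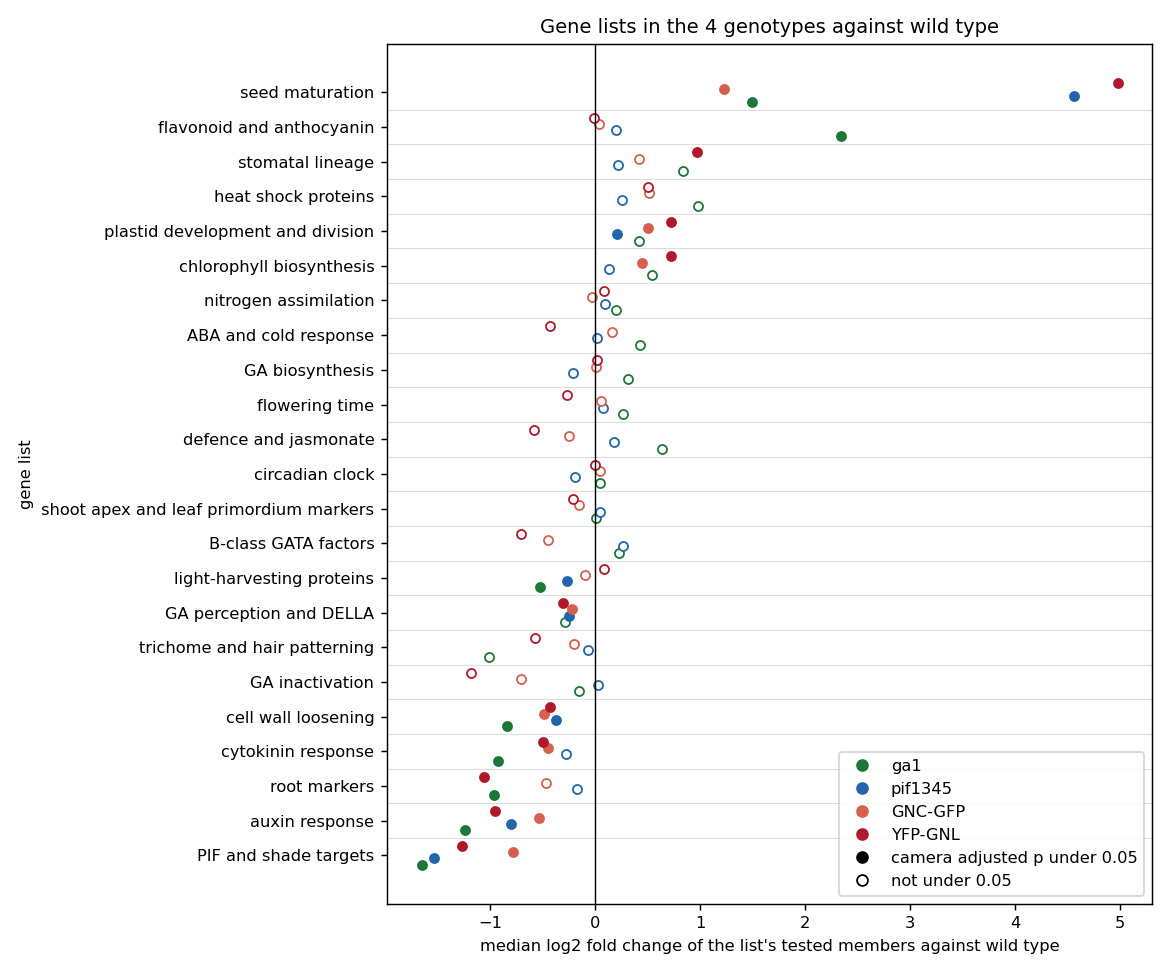
The horizontal axis is the median log2 fold change against wild type of the tested members of each of the 23 gene lists, with 1 point per genotype; filled points passed the camera test at its preset correlation and none of them passed with an estimated correlation. PIF and shade targets lie lowest, between -1.65 and -0.79, and seed maturation genes reach 4.56 in pif1345 and 4.98 in YFP-GNL.

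The GATA lines were then compared with each other. GNC-GFP had higher transcripts of PIF, shade and auxin response genes than YFP-GNL and lower transcripts of chlorophyll and seed maturation genes. Large differences were those of LHCB4.1 (log2 6.996 ± 0.10, GNC-GFP minus YFP-GNL), GNC (6.20 ± 0.12) and LTP4 (3.86 ± 0.52) on the higher side and GNL (-8.69 ± 0.12), SESA3 (-6.86 ± 0.71) and PAP85, a seed storage gene (-5.48 ± 0.71), on the lower. With slide as a block, which for this pair leaves the arrays of slide 4, these values were 6.93, 6.49, 2.55, -8.66, -8.22 and -5.88. All were past the threshold, with the spread taken from the other groups because slide 4 holds 1 YFP-GNL array. LTP4 was 4.515 without YFP-GNL replicate 1 and 3.24 without replicate 2, and SESA3 was -6.18 without replicate 1.

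Between the GATA lines, 13 of 22 PIF and shade targets were higher in GNC-GFP and none lower. The members had a median of 0.55 (camera adjusted p = 1.24e-05, adjusted p = 0.753 with an estimated correlation), with YUC8 at 1.05. FHL was higher too, but was not well above background on any YFP-GNL array, so its value is not given. Auxin response genes were higher for 15 of 23 (median 0.34, camera adjusted p = 9.06e-06, adjusted p = 0.753 with an estimated correlation). Seed maturation genes were lower for 13 of 18 (median -2.63, camera adjusted p = 2.55e-06, adjusted p = 0.753 with an estimated correlation) and chlorophyll biosynthesis genes for 16 of 24 (median -0.30, camera adjusted p = 4.05e-05, adjusted p = 0.753 with an estimated correlation). Plastid genes were lower for 8 of 16 (median -0.19, camera adjusted p = 0.0131, adjusted p = 0.753 with an estimated correlation) and stomatal lineage genes for 6 of 7 (median -0.54, camera adjusted p = 0.00269, adjusted p = 0.753 with an estimated correlation). Defence and jasmonate genes were higher for 4 of 9. All members together had a median of 1.12 (camera adjusted p = 0.0459, adjusted p = 0.753 with an estimated correlation). Members that passed included the vegetative storage gene VSP1 at 2.62. Root markers were higher for 5 of 18 (median 0.59, camera adjusted p = 0.0131, adjusted p = 0.821 with an estimated correlation). Adjusted over the list alone, the numbers were 18 for chlorophyll, 10 for plastid, 16 for auxin, 14 for seed maturation and 4 for root genes, and 4 defence genes were higher and 1 lower. With slide as a block, the medians were 0.48 for PIF and shade, 0.35 for auxin, -2.88 for seed maturation, -0.24 for chlorophyll, -0.21 for plastid, -0.56 for stomatal lineage and 0.94 for defence genes, with camera adjusted p from 1.92e-10 to 0.0446; the root marker call was lost (median 0.16, adjusted p = 0.391). The B-class GATA call was gained at the preset correlation, with 3 of 7 higher and 1 lower (median 0.27, adjusted p = 0.0154). The unblocked median was 0.32 (adjusted p = 0.124, adjusted p = 0.794 with an estimated correlation). This list includes the introduced genes GNC and GNL, at 6.49 and -8.66 with the block, so the call is not read as one of the whole family. In all 8600 genes passed between these lines, 4105 higher in GNC-GFP and 4495 lower, with 607 and 239 at least 2-fold. With slide as a block 1601 passed, 157 and 133 of them at least 2-fold higher and lower, and within slide 4, where YFP-GNL has 1 array, 200 passed.

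Both GATA lines were compared with ga1 directly, since the series sets them beside that mutant. Flavonoid and anthocyanin transcripts were lower in each GATA line than in ga1, for 16 of 16 genes both times. The median was -2.22 for GNC-GFP (camera adjusted p = 2.55e-06, adjusted p = 0.753 with an estimated correlation) and -2.11 for YFP-GNL (camera adjusted p = 9.06e-06, adjusted p = 0.753 with an estimated correlation), and with slide as a block it was -2.08 (adjusted p = 8.57e-07) and -1.93 (adjusted p = 3.21e-06). GSTF12 had values of -3.34 and -3.47 and UF3GT, an anthocyanin glycosyltransferase gene, of -3.56 and -4.38. Light-harvesting genes were higher than in ga1 for 14 of 20 and lower for 1 in GNC-GFP (median 0.37, camera adjusted p = 0.00226, adjusted p = 0.821 with an estimated correlation) and higher for 17 and lower for 2 in YFP-GNL. The median over the list was 0.56 (camera adjusted p = 0.00234, adjusted p = 0.821 with an estimated correlation), with blocked medians of 0.48 (adjusted p = 0.00354) and 0.59 (adjusted p = 0.0142).

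Auxin response genes were higher in GNC-GFP than in ga1 for 20 of 23 and lower for 1 (median 0.78, camera adjusted p = 1.24e-05, adjusted p = 0.753 with an estimated correlation), and PIF and shade targets for 16 of 22, with 1 lower (median 0.82, camera adjusted p = 0.00138, adjusted p = 0.754 with an estimated correlation). IAA29, in both lists, had a value of 2.62 and PIL1 of 2.29. Blocked by slide, the medians were 0.59 (adjusted p = 0.00193) and 0.70 (adjusted p = 0.0116). Seed maturation genes passed only with the block, with 6 of 18 lower and 1 higher in GNC-GFP (median -1.67, adjusted p = 0.0459; unblocked -0.10, adjusted p = 0.830). This value is indirect, through YFP-GNL replicate 1 and pif1345 replicate 3. Their storage gene medians, -0.11 and -1.56, differ from the other arrays of their lines (-0.83 and -1.85 in YFP-GNL, -0.12 and 1.16 in pif1345), so no difference is read from the gained call. In YFP-GNL against ga1, auxin response genes were higher for 13 and lower for 2 of 23 (median 0.42, camera adjusted p = 0.0475, adjusted p = 0.843 with an estimated correlation), a call lost with slide as a block (median 0.38, adjusted p = 0.222). Plastid genes were higher for 9 of 16 (median 0.27, camera adjusted p = 0.00979, adjusted p = 0.753 with an estimated correlation; blocked median 0.27, adjusted p = 0.0446), with the division genes PDV2 at 1.05 and PDV1 at 0.79. The other lists past the threshold for YFP-GNL lost it with slide as a block. They were chlorophyll biosynthesis, 15 higher and 2 lower of 24 (median 0.28, camera adjusted p = 0.0350, adjusted p = 0.821 with an estimated correlation, blocked median 0.23, adjusted p = 0.207), seed maturation, 13 higher and 1 lower of 18 (median 2.41, camera adjusted p = 0.00987, adjusted p = 0.794 with an estimated correlation, blocked median 1.015, adjusted p = 0.222), and B-class GATA factors, 1 higher and 6 lower of 7 (median -1.37, camera adjusted p = 0.0289, adjusted p = 0.753 with an estimated correlation, blocked median -0.55, adjusted p = 0.0541). Adjusted over the list alone, 16 chlorophyll genes were higher and 2 lower, and the other numbers against ga1 were the same.

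Of single genes, ESP (AT1G54040) was lower than in ga1 by log2 values of -7.29 ± 0.21 in GNC-GFP and -8.38 ± 0.21 in YFP-GNL, with -7.04 and -7.95 when blocked by slide. SQN had a value of -5.13 ± 0.17 in GNC-GFP, and CORI3 and LHCB4.1 had -7.96 ± 0.22 and -6.77 ± 0.10 in YFP-GNL. DELTA-VPE, a vacuolar protease gene, was higher than in ga1 by 5.54 ± 0.55 in GNC-GFP and 6.70 ± 0.55 in YFP-GNL, with 4.66 and 5.83 without ga1 replicate 2 and 6.21 and 7.37 without ga1 replicate 3. MRN1 (7.18 ± 0.93), IRT1 (5.30 ± 0.73) and LCR67 (-4.86 ± 1.05) passed in GNC-GFP against ga1 but not with slide as a block, where they had 3.74 ± 1.71, 5.45 ± 1.85 and -3.19 ± 2.07 (adjusted p = 0.136, 0.0535 and 0.288). Without ga1 replicate 2 the IRT1 value was 6.48, and without replicate 3 it was 4.61. In all, 13711 genes passed for GNC-GFP, 6422 higher and 7289 lower than in ga1, and 14713 for YFP-GNL, 7318 higher and 7395 lower. Blocked by slide the totals were 5999 and 9316.

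Compared with pif1345, the GATA lines had the PIF transcripts themselves at higher levels, with PIF5 at 6.53 ± 0.10 in GNC-GFP and 6.34 ± 0.10 in YFP-GNL and PIF1 at 4.82 and 4.64. Chlorophyll genes were higher in both lines. In YFP-GNL 21 of 24 were higher and 1 lower (median 0.54, camera adjusted p = 3.75e-04, adjusted p = 0.753 with an estimated correlation; blocked median 0.52, adjusted p = 6.50e-04), with HEMD at 0.74 and POR C at 0.74. In GNC-GFP 11 were higher and 2 lower (median 0.19, camera adjusted p = 0.0475, adjusted p = 0.821 with an estimated correlation; blocked median 0.24, adjusted p = 0.0248). Seed maturation genes were lower in GNC-GFP than in pif1345 for 9 of 18 and higher for 1 (median -1.61, camera adjusted p = 0.00643, adjusted p = 0.754 with an estimated correlation; blocked median -2.44, adjusted p = 2.63e-04). SESA3 had a value of -8.06 ± 0.71 and CRU2 of -7.35 ± 0.87, and CRU2 was -6.69 without pif1345 replicate 2 and -8.03 without replicate 3. With slide as a block, an indirect value through YFP-GNL replicate 1, they were -10.61 ± 1.03 and -10.84 ± 1.11. Only with the block did light-harvesting genes pass as higher in GNC-GFP, 3 of 20 (median 0.29, adjusted p = 0.0290; unblocked 0.10, adjusted p = 0.208). The same held for root markers, of which 4 of 18 were lower (median -0.91, adjusted p = 0.0142; unblocked -0.26, adjusted p = 0.236). Both gained calls are indirect and rest on YFP-GNL replicate 1 as the only link. They were tested at the preset correlation only. Unblocked with an estimated correlation, the camera adjusted p was 0.942 for light-harvesting genes and 0.913 for root markers.

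Auxin response genes were higher in GNC-GFP than in pif1345 for 15 and lower for 1 of 23 (median 0.33, camera adjusted p = 0.00153, adjusted p = 0.821 with an estimated correlation; blocked median 0.43, adjusted p = 0.0290), and PIF and shade targets higher for 11 and lower for 2 of 22 (median 0.35, camera adjusted p = 0.0144, adjusted p = 0.821 with an estimated correlation; blocked median 0.31, adjusted p = 0.0428), with PIL1 at 3.22 and IAA29 at 3.14. B-class GATA genes were higher for 1 and lower for 5 of 7 in GNC-GFP (median -0.72, camera adjusted p = 0.0210, adjusted p = 0.753 with an estimated correlation), a call lost with slide as a block (median -0.58, adjusted p = 0.207), and higher for 1 and lower for 6 in YFP-GNL (median -0.97, camera adjusted p = 0.0210, adjusted p = 0.753 with an estimated correlation; blocked median -0.85, adjusted p = 0.0319). In YFP-GNL, plastid genes were higher for 12 and lower for 1 of 16 (median 0.41, camera adjusted p = 0.0131, adjusted p = 0.753 with an estimated correlation; blocked median 0.39, adjusted p = 0.0290). All 7 stomatal lineage genes were higher (median 0.75, camera adjusted p = 0.00979, adjusted p = 0.753 with an estimated correlation; blocked median 0.88, adjusted p = 0.00723), and root markers were lower for 14 of 18 (median -0.78, camera adjusted p = 0.0131, adjusted p = 0.821 with an estimated correlation; blocked median -0.93, adjusted p = 0.00490). Adjusted over the list alone, 13 chlorophyll genes were higher and 2 lower and 11 PIF targets higher and 3 lower in GNC-GFP, 15 root markers were lower in YFP-GNL, and the other numbers were the same. In all, 10860 genes passed between GNC-GFP and pif1345, 5744 higher and 5116 lower, and 5464 with slide as a block. Between YFP-GNL and pif1345 14745 passed, 7755 higher and 6990 lower, with 14028 when blocked and 10753 within slide 3.

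The mutants differed from each other in flavonoid genes, of which 14 of 16 were higher in ga1 than in pif1345 (median 2.095, camera adjusted p = 9.06e-06, adjusted p = 0.753 with an estimated correlation; blocked median 2.14, adjusted p = 3.21e-06), with GSTF12 at 3.87 and TT8 at 2.98. Cytokinin response genes were lower in ga1 for 9 of 13 (median -0.36, camera adjusted p = 0.0131, adjusted p = 0.753 with an estimated correlation; blocked median -0.45, adjusted p = 0.0216), seed maturation genes for 9 of 18 (median -1.52, camera adjusted p = 0.0144, adjusted p = 0.821 with an estimated correlation; blocked median -0.87, adjusted p = 0.0473) and root markers for 13 of 18 with 2 higher (median -0.80, camera adjusted p = 0.0350, adjusted p = 0.821 with an estimated correlation; blocked median -0.85, adjusted p = 0.0473). The remaining lists past the threshold lost it with slide as a block. They were light-harvesting proteins, 1 higher and 12 lower of 20 (median -0.25, camera adjusted p = 0.0248, adjusted p = 0.843 with an estimated correlation, blocked median -0.28, adjusted p = 0.0775), stomatal lineage, 6 higher and 1 lower of 7 (median 0.62, camera adjusted p = 0.0369, adjusted p = 0.754 with an estimated correlation, blocked median 0.59, adjusted p = 0.0720), and trichome and hair patterning, 1 higher and 5 lower of 7 (median -0.76, camera adjusted p = 0.0475, adjusted p = 0.753 with an estimated correlation, blocked median -0.75, adjusted p = 0.0603). Chlorophyll genes passed only with the block, 15 of 24 higher in ga1 and 4 lower (median 0.32, adjusted p = 0.0154). Unblocked, the median was 0.27 (camera adjusted p = 0.0829, adjusted p = 0.821 with an estimated correlation). The blocked test used the preset correlation only. When adjusted over each list alone, 10 cytokinin genes were lower and the other numbers were the same. ESP (AT1G54040) was higher in ga1 by 7.67 ± 0.21 and SESA3 and MRN1 lower, at -7.33 ± 0.71 and -6.86 ± 0.93. Within slide 2, where pif1345 has 1 array, these values were 7.32, -6.31 and -6.78. In all, 13467 genes passed, 7370 higher in ga1 and 6097 lower, with 9996 when blocked by slide and 7635 within slide 2.

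Changes shared between genotypes were counted last. GNC-GFP and YFP-GNL shared 13027 genes called in the same direction against wild type, 7289 higher and 5738 lower, and 75 called in opposite directions. Independent lists of these sizes would share 5508 genes, and simulated unchanged groups against the same controls shared 0. Their fold changes correlated across genes at r = 0.87, against a simulated 0.50, and the covariance was 0.593 against a simulated 0.0174. Genes are not independent replicates, and part of the excess may come from the 3 shared wild type arrays, which are too few to split. The simulations held no changed genes and no slide offset. They could therefore hardly share calls, and they do not cover a property of slide 1. Shared increases included MPK10 (log2 4.05 and 5.63), UGT74E2 (3.84 and 3.86) and DELTA-VPE (3.54 and 4.71), and shared decreases included ASN1 (-2.88 and -3.66), HFR1 (-2.50 and -3.11) and SYP112 (-2.20 and -2.54).

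GNC-GFP shared 9655 genes with ga1 in the same direction (independent lists 5469, opposite 1735, r = 0.58, covariance 0.403), among them GPT2 (log2 3.42 and 5.60) and PAR1 (-2.15 and -2.06). YFP-GNL shared 10939 with ga1 (independent lists 6357, opposite 2057, r = 0.57, covariance 0.536), among them GA20OX3 (3.49 and 3.47) and NSP3 (-3.33 and -4.33). With pif1345, GNC-GFP shared 6528 genes (independent lists 2919, opposite 535, r = 0.67, covariance 0.245) and YFP-GNL 6878 (independent lists 3385, opposite 673, r = 0.64, covariance 0.313), such as YUC8 (-2.24 in YFP-GNL and -2.22 in pif1345). The mutants shared 7255 genes (independent lists 3376, opposite 490, r = 0.63, covariance 0.317), such as MES18 (3.53 in ga1 and 2.63 in pif1345) and IAA29 (-3.44 and -3.96). The simulated r was 0.50 and the simulated covariance 0.017 for each pair. As above, that r follows from the shared control and is not a reference value for these pairs. In all 4 genotypes 3612 genes were higher and 1815 lower than in wild type, and 504 and 82 genes were so at 2-fold or more. These contrasts share the wild type arrays of slide 1, so no excess is read from these numbers. ASN1 fell in all 4 (log2 -4.64 in ga1, -2.21 in pif1345, -2.88 in GNC-GFP and -3.66 in YFP-GNL), and so did HFR1, PAR1, HB4 and YUC9.

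**Figure D5:**
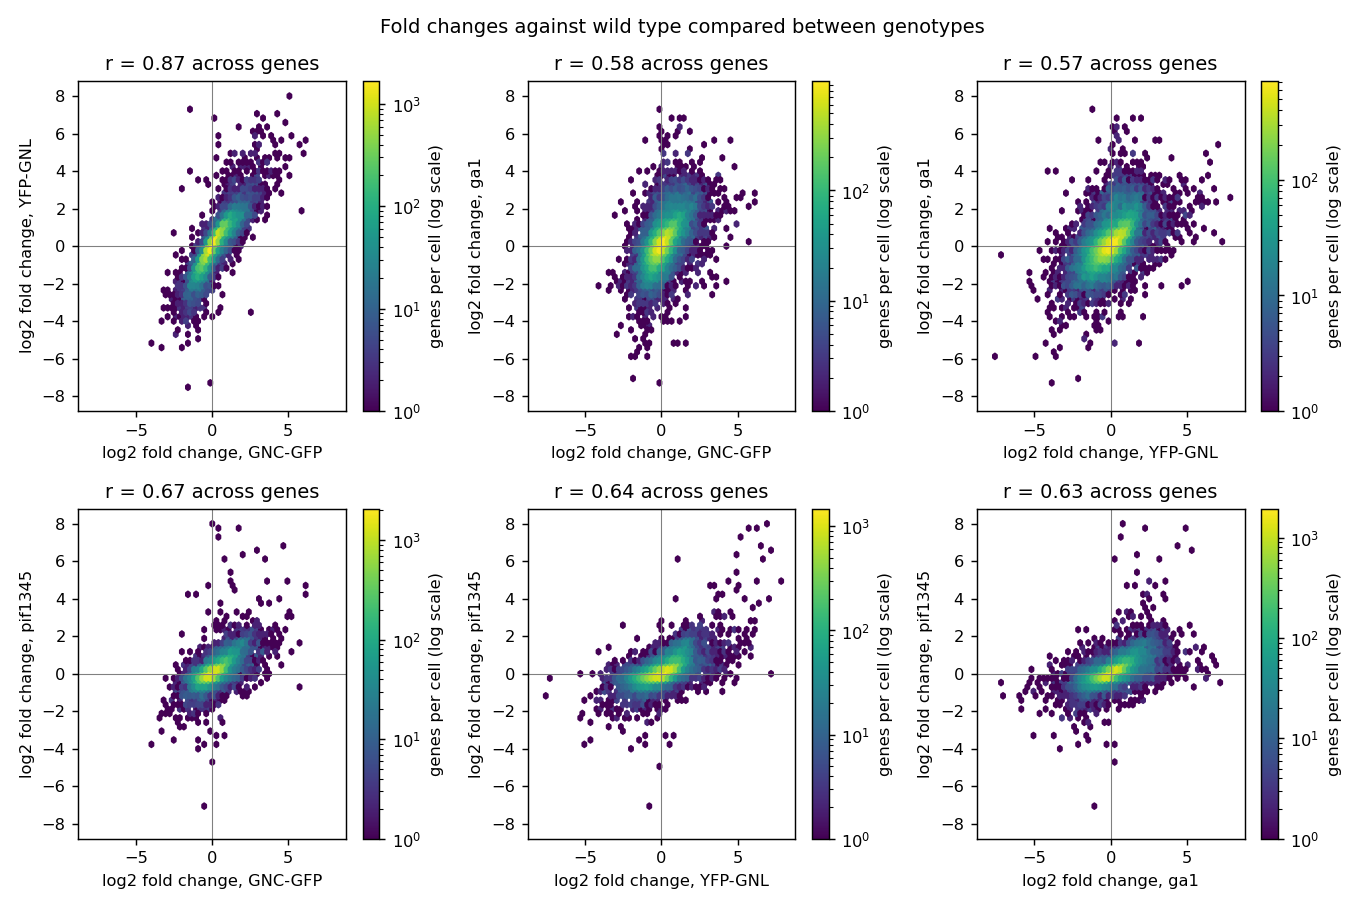
Each panel sets the log2 fold changes against wild type of a pair of genotypes against each other, with colour giving the number of genes per cell on a log scale. The correlation across genes is 0.87 for GNC-GFP with YFP-GNL and between 0.57 and 0.67 for the other pairs. Simulated unchanged groups gave 0.50 through the shared control alone, which is not a reference value for genotypes with changed genes.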

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

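Here the tests of albumin probes and of probe sequence differences, and the criterion that voids the normexp test, were chosen only after the result was seen. Among the 6601 tested probes without a gene name here, which no comparison of the report uses, a signal higher than in the wild type arrays appeared in each genotype. At 2-fold or more with limma adjusted p under 0.05, 2089 were higher in ga1, 681 in pif1345, 1276 in GNC-GFP and 1262 in YFP-GNL, and 377, 44, 133 and 379 were lower. Of these tested probes, 34.3% were no brighter than the dimmest 10% of genes.

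The dimmest 10% of tested genes lay higher in each genotype than in wild type, with a median log2 fold change of 1.17 in ga1, 0.537 in pif1345, 0.793 in GNC-GFP and 0.627 in YFP-GNL. Arrays of pif1345 on slides 2 and 3 differed over these genes by a median of 0.51 and those of YFP-GNL on slides 4 and 3 by 0.32, whereas genotypes on 1 slide differed by -0.0569 (slide 2, ga1 minus pif1345), 0.14 (slide 3, YFP-GNL minus pif1345) and -0.0299 (slide 4, GNC-GFP minus YFP-GNL). Selection by the filter may also contribute, since over the dimmest 10% of all loci without the filter the medians were 0.0796, 0.17, -0.0884 and 0.379. With normexp the ga1 median was 0.0433, which met the outcome written beforehand for background subtraction as the cause, but normexp shrank the interquartile range of GNC-GFP against pif1345 over these genes to 28.1%, so background subtraction cannot be told apart from this shrinkage. A slide offset and filter selection both stay open, slide 1 holds wild type alone, and no biological explanation was tested.

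Seed storage protein and oleosin transcripts, 11 genes, had a median log2 fold change against wild type of 6.695 in pif1345 and 6.325 in YFP-GNL (6.35 and 5.85 with SESA1, below background in wild type, at its bound), against 2.33 in ga1 and 2.105 in GNC-GFP. Dry or ungerminated seeds in the pif1345 samples are argued against only by 16 tested LEA transcripts of dry seeds (19 listed). Their median was 0.00596 (quartiles -0.27 to 0.58), with 1 of 16 higher. These genes were chosen after their values, or those of related genes, were seen. The seed maturation list, where 16 of 18 genes rose in pif1345 and none fell, also holds PER1, at 2.28. Dry seeds are therefore not ruled out in pif1345. In YFP-GNL the LEA median was 3.27 (quartiles 2.88 to 4.42, 16 of 16 higher), a share of 0.517 of the storage median, or 0.559 with the bound, where 0.5 had been set for such seeds; with LEA medians of 1.14 in ga1 (10 of 16 higher, share 0.49) and 1.93 in GNC-GFP (12 of 16, share 0.918), this source stays open in these 3 genotypes. The 6 cruciferin and oleosin genes, not albumins, had medians of 5.49 in pif1345 and 6.11 in YFP-GNL. They cannot show if probes read several albumin genes. A slower loss of storage transcripts in these genotypes may be proposed as a hypothesis and was not tested. Slide 1 takes no part in the differences on 1 slide over the seed maturation list. Those were -2.88 for GNC-GFP minus YFP-GNL on slide 4 and -0.87 for ga1 minus pif1345 on slide 2. Each rests on 1 array of a line, YFP-GNL replicate 1 and pif1345 replicate 3. Their storage medians, -0.11 and -1.56, were the highest of YFP-GNL and the lowest of pif1345.

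Some genes were close to switched on or off in ga1: ESP (AT1G54040) at 7.22, FLC at -3.85 and MRN1 at -7.22 against wild type. In pif1345, GNC-GFP and YFP-GNL the values were -0.45, -0.07 and -1.16 for ESP, -0.88, -0.62 and -0.56 for FLC, and -0.36, -0.05 and -3.78 for MRN1, the last -4.89 without YFP-GNL replicate 1 and -2.36 without replicate 2. A segment of another accession around GA1 was not decided: 12 of the 200 nearest tested loci were called at 4-fold or more against 1226 of 22250 others (odds ratio 1.09, 95% interval 0.554 to 1.97, Fisher's exact p = 0.754). AOP3, named beforehand, had no tested probe, and AOP1 (AT4G03070) rose by 0.98 in ga1. ESP, FLC (AT5G10140) and MRN1 (AT5G42600) lie on other chromosomes than GA1 (AT4G02780), so such a segment could not contain them. Sequence differences under the probes may contribute to calls in ga1. Of 6454 loci, 312 had probes called in opposite directions in ga1 against 139 in YFP-GNL (ratio 2.24), with 53 in pif1345 and 137 in GNC-GFP. This count is over all loci and does not test ESP, FLC or MRN1 themselves. The ESP probes rose together in ga1, at 9.95, 7.57 and 7.22. The effect of GA deficiency itself stays open as an untested biological explanation.

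In YFP-GNL the probes of LHCB4.1 had values of -7.97, -7.22, -6.99, -3.81 and -0.96, and the 6 neighbouring loci TAAC, RUS5, AIRP2, LECRKA4.1, LECRKA4.2 and LECRKA4.3 had -0.21, 0.94, -0.93, 3.56, -0.88 and 0.15, the last not past the threshold. LECRKA4.1 also rose in ga1 (2.705), pif1345 (1.515) and GNC-GFP (2.658), so its rise is not particular to YFP-GNL.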

How the results depend on the processing

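The fits within 1 slide, those without the dimmest 10% of genes and normexp without dust-covered control spots were chosen only after the result was seen. Against wild type, the number of genes past the threshold stayed within 1.5 times of the reported one under every alternative run, except for normexp fitted on all spots. Lowest and highest values over single left-out arrays were 15411 and 17210 for ga1, 5985 and 9675 for pif1345, 12776 and 15196 for GNC-GFP and 15876 and 17154 for YFP-GNL. Leaving out 1 array gave 5847 to 8662 for GNC-GFP against YFP-GNL, 12370 to 12958 for GNC-GFP and 13459 to 14330 for YFP-GNL against ga1, 8858 to 10448 and 13614 to 14403 for these lines against pif1345, and 11557 to 13188 for ga1 against pif1345. Shared calls ranged from 11628 to 13537 for GNC-GFP and YFP-GNL, 8304 to 9394 for GNC-GFP and ga1, 9776 to 11108 for YFP-GNL and ga1, 4440 to 6491 for GNC-GFP and pif1345, 4725 to 7344 for YFP-GNL and pif1345, and 4949 to 7216 for ga1 and pif1345, each lowest without wild type replicate 2. List tests past the threshold ranged from 31 to 37.

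Numbers for direct contrasts depended on how the slide was modelled. With slide as a fixed block 1601 genes passed for GNC-GFP against YFP-GNL, 5999 for GNC-GFP against ga1, 9316 for YFP-GNL against ga1 and 5464 for GNC-GFP against pif1345, where 8600, 13711, 14713 and 10860 had passed, while YFP-GNL against pif1345 had 14028 against 14745. This block also costs precision: the standard error of LHCB4.1 between the GATA lines rose from 0.10 to 0.156 while its value went from 6.996 to 6.93. LTP4 moved from 3.86 to 2.55, and was 4.515 without YFP-GNL replicate 1, the only YFP-GNL array on slide 4, and 3.24 without replicate 2. Lost precision, single arrays and slide differences all stay open as causes. Within slide 4, 200 passed for GNC-GFP against YFP-GNL, and within slide 2, 7635 for ga1 against pif1345 against 13467 over all arrays; these fits have fewer arrays. With only the groups compared, 4465 passed for GNC-GFP against YFP-GNL; this fit also has fewer arrays. With slide as a random block (consensus correlation 0.0383) 8201, 13258, 14333, 10506, 14761 and 13234 genes passed for the direct contrasts in the order of the report. The slide was not used as a block for gene lists against wild type.

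With an estimated correlation 0 of 92 list tests against wild type passed with limma's camera, where 33 had passed, and 7 had an unadjusted p under 0.05; of 138 direct tests 0 passed where 36 had, with 3 at an unadjusted p under 0.05. Of 507 named gene values, 501 past the threshold, 5 reversed under some alternative and 36 fell short of the threshold under some alternative; apart from the estimated correlation 5 of the 33 list calls were lost under some alternative. ATGA2OX3 reversed with normexp in ga1 (-0.25), pif1345 (-0.17) and GNC-GFP (-0.054) and with quantile normalization in ga1 (-0.28). RAB18 (AT5G66400) reversed with the mean of all probes in pif1345 (-0.44) and GNC-GFP (-0.38). The cause was not tested.

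The normexp correction first fitted on all spots gave 9050, 2335, 6992 and 10647 genes for ga1, pif1345, GNC-GFP and YFP-GNL against wild type. It was judged to have failed on YFP-GNL replicate 1 and was replaced after these numbers were seen. The 4 control spots then left out had a local background over 100 units above their own signal, which is read here as dust. Without these spots 15407, 7243, 13391 and 16321 genes passed. The 2-fold increases and decreases were then 1239 and 1434 in ga1, 152 and 152 in pif1345, 605 and 508 in GNC-GFP, and 1448 and 1527 in YFP-GNL, so that in ga1 and YFP-GNL, as with quantile normalization, decreases outnumbered increases. No scaling moved the share of higher calls by over 10 points. The median of all genes shifted to 0.143 in YFP-GNL without the filter and to 0.102 in ga1 with the mean of all probes.

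The replicate numbers do not pair the samples: same-number correlations ran from -0.28 to 0.223, with 5 of 30 over 0.1, and 3 of 15 arrays correlated best with their own number. With the replicate block 16429, 8215, 14199, 16725, 7920, 13349, 14347, 10402, 14477 and 12991 genes passed for the contrasts in the order of the report, and the block changed no named gene or list call. Signal over background limits what can be measured for dim genes.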

Other observations

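Each test in this part was planned, and the genes named for lists follow the rule set beforehand. Several lists, some of them described in the report for other comparisons, held genes that moved in opposite directions, and none of the list tests in this and the next paragraph passed. Stomatal lineage genes rose for 6 and fell for 1 of 7 in ga1 (median 0.84, camera adjusted p = 0.0595), with BASL at 1.77 and MUTE at 1.46. In pif1345 they rose for 1 and fell for 1 (median 0.22, camera adjusted p = 0.556), and in GNC-GFP they rose for 4 and fell for 1 (median 0.42, camera adjusted p = 0.176). Trichome and hair patterning genes rose for 2 and fell for 5 of 7 in ga1 (median -1.01, camera adjusted p = 0.0529), with MYB0 at -2.07, fell for 1 in pif1345 (median -0.07, camera adjusted p = 0.361) and 3 in GNC-GFP (median -0.20, camera adjusted p = 0.0703), and rose for 1 and fell for 4 in YFP-GNL (median -0.57, camera adjusted p = 0.141). Shoot apex and leaf primordium markers rose for 4 and fell for 3 of 10 in ga1 (median 0.01, test directed down, camera adjusted p = 0.889), 3 and 1 in pif1345 (median 0.05, camera adjusted p = 0.836), 2 and 5 in GNC-GFP (median -0.15, camera adjusted p = 0.323), and 3 and 5 in YFP-GNL (median -0.21, camera adjusted p = 0.495). The stem cell gene CLV3 rose in GNC-GFP (1.06) and YFP-GNL (1.02). Flowering time genes rose for 9 and fell for 7 of 18 in ga1 (median 0.26, mean -0.03, test directed down, camera adjusted p = 0.796), 4 and 3 in pif1345 (median 0.07, camera adjusted p = 0.811), 6 and 4 in GNC-GFP (median 0.06, camera adjusted p = 0.744), and 5 and 7 in YFP-GNL (median -0.26, camera adjusted p = 0.744). MAF4, a relative of FLC, rose in YFP-GNL (2.68), GNC-GFP (2.02) and pif1345 (0.80).

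Circadian clock genes rose for 8 and fell for 8 of 18 in ga1 (median 0.05, mean -0.06, camera adjusted p = 0.674), 6 and 9 in pif1345 (median -0.19, camera adjusted p = 0.374), 5 and 4 in GNC-GFP (median 0.05, camera adjusted p = 0.847), and 4 and 3 in YFP-GNL (median -0.00, test directed up, camera adjusted p = 0.995). PRR3 rose in ga1 (2.34), GNC-GFP (1.55) and YFP-GNL (1.32), and also in pif1345 (1.09). LNK2 fell in pif1345 (-1.52). Heat shock protein genes rose for 6 of 8 in ga1 (median 0.98, camera adjusted p = 0.0895), 3 in pif1345 (median 0.26, camera adjusted p = 0.322), and for 4 against 1 that fell in GNC-GFP (median 0.51, camera adjusted p = 0.632) and in YFP-GNL (median 0.50, camera adjusted p = 0.707). Nitrogen assimilation genes rose for 7 and fell for 5 of 13 in ga1 (median 0.20, mean -0.13, camera adjusted p = 0.957), 6 and 4 in pif1345 (median 0.09, camera adjusted p = 0.556), 3 and 1 in GNC-GFP (median -0.03, camera adjusted p = 0.849), and 4 and 4 in YFP-GNL (median 0.09, mean -0.34, camera adjusted p = 0.889). ABA and cold response genes rose for 6 and fell for 2 of 10 in ga1 (median 0.43, camera adjusted p = 0.605), rose for 2 in pif1345 (median 0.02, camera adjusted p = 0.805), rose for 4 and fell for 2 in GNC-GFP (median 0.16, camera adjusted p = 0.556), and rose for 4 and fell for 6 in YFP-GNL (median -0.43, mean 0.12, test directed down, camera adjusted p = 0.806). Defence and jasmonate genes rose for 5 and fell for 2 of 9 in ga1 (median 0.63, camera adjusted p = 0.978), rose for 1 in pif1345 (median 0.18, camera adjusted p = 0.744), rose for 3 and fell for 1 in GNC-GFP (median -0.25, mean 0.32, camera adjusted p = 0.849), and rose for 2 and fell for 4 in YFP-GNL (median -0.58, camera adjusted p = 0.374). VSP1 fell in ga1 (-2.83) and YFP-GNL (-3.33), and the defence gene BGL2 was at least 13.2-fold higher in YFP-GNL. With p adjusted over each list alone, no number given for these lists moved by more than 1 gene.

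Other splits of the arrays were counted on genes without missing values. For each of the 10 contrasts 1 of 10 splits, the real one, gave as many genes, the highest other split gave 0, and 10 splits are too few for a share under 0.05. The real split gave 16790 genes for ga1, 8691 for pif1345, 15242 for GNC-GFP and 15883 for YFP-GNL against wild type. It gave 4462 for GNC-GFP against YFP-GNL, 14007 and 13117 for GNC-GFP and YFP-GNL against ga1, 10966 and 12979 against pif1345, and 12828 for ga1 against pif1345. For shared calls 100 splits of 9 arrays were drawn, and the share was under 0.05 for each pair. For 4 pairs no other drawn split gave as many, while for pif1345 with either GATA line mixed splits gave more than the real one. No exclusion of chance is read for any pair. The wild type arrays are alone on slide 1, so the arrays cannot be exchanged freely between groups. None of these numbers bears on whether the genotypes of a pair resemble each other. As many calls came from 1 split for GNC-GFP and YFP-GNL (12649, highest other 6125), 1 for GNC-GFP and ga1 (10345, highest other 9915), 1 for YFP-GNL and ga1 (10466, highest other 7535), 3 for GNC-GFP and pif1345 (6931, highest other 7157), 2 for YFP-GNL and pif1345 (5845, highest other 11159), and 1 for ga1 and pif1345 (7468, highest other 2291). The highest other splits of GNC-GFP and YFP-GNL and of GNC-GFP and ga1 exchange whole groups. Those of GNC-GFP and pif1345 and of YFP-GNL and pif1345, which exceed the real number, set the 3 arrays of the GATA line as the control against mixtures of wild type and pif1345 arrays. Both point to a structure of the samples, in which any control group that differs from the rest gives shared calls. In the split that gave 11159, the pif1345 arrays are also parted by slide; the shared calls against wild type cannot be blocked by slide. For gene lists 4 of 100 splits of the 15 arrays gave as many as 33 calls, with 35 as the highest other.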
